A study of Homo sapiens with 6 samples.

How the data were processed

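The samples were human type 2 innate lymphoid cells (ILC2s) expanded in culture, of which 3 had received IL-15 and 3 had not. Per the labels' protocols, all cultures held IL-2 at 500 IU/ml, IL-7 at 20 ng/ml and 10% human AB serum, and cells were moved onto fresh OP9 stroma as they grew. Cells were sorted, and cDNA was made from 2 ng of total RNA with the SMART-Seq v4 kit, sheared by sonication and built into libraries with a KAPA kit, per the labels' protocols. Reads were single and 51 cycles long on an Illumina HiSeq instrument, per the labels' protocols. SMART-Seq cDNA does not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. This applies to overlapping genes in general, and whether strand entered the counting is not given in the sources used here.

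The authors deposited 1 table of whole-number read counts for 25168 gene symbols, with chromosome, start, end and a gene length in kb, per the file headers. The aligner, the counting tool, the gene annotation and the genome build are not given in the sources used here. Of the symbols, 23268 were found in a RefSeq table of GRCh38.p14, 23248 of them on the same chromosome. Starts lay within 5 kb of the RefSeq start for 90.8% of these and were identical for 34.0%, so coordinates are printed as the deposited table gives them, with no build named. The table holds no symbols of mitochondrially encoded genes, and the planned share and gene list of these were not analysed here.

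Groups were taken from the source label of each sample and replicate numbers (10, 11 and 12) from the titles. Genes of the Y chromosome, XIST and TSIX (78 symbols) were removed before any test. The main comparison used edgeR 4.0.16 (R 4.3.3) on the deposited counts with TMM factors, edgeR's default low-count filter by group, the robust quasi-likelihood F test and Benjamini-Hochberg adjustment, with group as the only term and a threshold of 0.05. This left 13581 genes. CPM given in the text are scaled by the TMM factors unless counts of a whole library are named. Standard errors (SE) of log2 fold changes are the size of the fold change divided by the square root of F. Expression values are means ± SD with n = 3 libraries per group.

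Because both groups carry the numbers 10, 11 and 12, a comparison with the number as a block (the paired comparison) was planned as an alternative. Deviations from the group means of same-numbered libraries correlated across genes at 0.58, 0.67 and 0.67, against at most -0.20 for libraries of different numbers. Deviations cancel out within a group for each gene, so positive same-number values by themselves push the others negative. The first principal components, with 38.7% and 36.4% of the variance, separated the numbers. By a rule set in advance (each pair's correlation above 0.1) the numbers pair the samples; the pairing comes from the titles, and the labels do not say what a number marks. The call counts of both comparisons were on view when this rule was applied. The coefficient of variation beyond counting error was 16.0% without the block and 6.57% with it. No libraries were duplicates: chi-square per degree of freedom between libraries ranged from 6.41 to 39.4, over genes with at least 20 counts in a pair.

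Gene lists and cell type markers were fixed before the data were examined. Of 25 lists, 22 kept at least 3 measured members. They were tested with limma's camera 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera takes its degrees of freedom from the 6 libraries and not from the genes. No list passed there in either comparison, so that test cannot show that a list is unchanged. Named genes followed a rule fixed at the same time: 13 genes of the ILC2 and cytotoxic programmes, the 8 largest changes in each direction among genes past the threshold with at least 10 CPM and groups that did not overlap, and, from each list, up to 3 members that passed or otherwise the 2 most abundant. Since the main comparison had no calls, the part of the rule on the largest changes and on list members that passed was applied to the paired comparison, and its 36 calls were all named; both choices were made after values were seen, as was the naming of list members outside the rule.

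GC content per symbol came from the longest GENCODE transcript of that symbol, for 96.5% of tested genes. Trends with GC content and with the deposited gene length were measured over genes above a log2 CPM of 3. GC trends were removed with a lowess curve (span 0.3, genes above a log2 CPM of 1) for each library, entered as offsets in the paired comparison.

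The procedure was tested on simulated counts built from the gene means, number effects and dispersions of these libraries, with 13414 genes tested. For IL-15 against no IL-15 without the block it recovered 58% of genes changed 1.5-fold and 86% of those changed 2-fold, with 0 unchanged genes called. With the block it recovered 99% at both sizes, with 13 unchanged genes called. A simulated list of 20 genes raised 1.2-fold was found with and without the block, and none of 20 unchanged lists was called. Simulated genes were drawn independently of one another, so the lists held no correlation between genes. The simulation therefore does not test the preset correlation on lists whose members vary together.

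Library totals, genes detected and the share of counts in the 50 most abundant genes were compared by exact two-sided permutation tests of the group means; all other tests were two-sided as well. A count of 0 is given with the level that 3 counts of the library total would make, and such limits cover counting error only, since reads carry no molecular identifiers. Alternatives were RLE factors, total counts alone, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (5 CPM in 3 libraries), the block, an adjusted p of 0.01, a minimum fold of 2 and leaving out each library. A test of the source of the MS4A1 signal is not reported here. The same set of alternatives in the paired comparison, leaving out both libraries of a number, and removal of the GC trend were added after seeing the data.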

Results

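The data describe ILC2s, lymphocytes known for GATA3-dependent secretion of type 2 cytokines, grown on OP9 cells, a mouse bone marrow stromal line. The contrast is the addition of IL-15 at 20 ng/ml, a cytokine that signals through the beta and gamma chains of the IL-2 receptor, to medium that already held IL-2 and IL-7. There were 3 libraries with IL-15 and 3 without, numbered 10, 11 and 12 in each group. Total counts for numbers 10, 11 and 12 were 26720879, 28514162 and 31141773 with IL-15 and 35228606, 28584241 and 28279046 without. No difference was found in total counts (two-sided exact permutation p = 0.6) or in genes detected, 16437 ± 176 with and 16495 ± 104 without IL-15 (SD, n = 3, two-sided exact permutation p = 0.8). The 50 most abundant genes took 14.1% ± 0.714 of counts with and 13.8% ± 0.666 without IL-15 (two-sided exact permutation p = 0.6, where 3 against 3 libraries cannot go below 0.1). The labels do not say that the libraries came from separate donors or cultures, so p-values without the block measure the spread between these samples. In the paired comparison p-values measure the spread of the difference with against without IL-15 over these pairs.

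Without IL-15 the cells carried the RNA of ILC2 regulators and receptors. KIT, the stem cell factor receptor, stood at 2341 ± 455 CPM (SD, n = 3), PTGDR2, the prostaglandin D2 receptor CRTH2, at 1791 ± 77.2 CPM and GATA3 at 900 ± 20.1 CPM. The cytokine genes LIF and IL13 were at 1090 ± 131 and 95.7 ± 27.8 CPM. IL5 gave 20 counts and IFNG 2 counts over all 6 libraries. IL9 gave 0 counts in every library, which allows up to 0.0852 to 0.112 CPM. Of the cytotoxic granule genes, PRF1 (perforin) was at 336 ± 24.8 CPM, GZMB (granzyme B) at 27.4 ± 17.9 CPM and GZMA (granzyme A) at 8.99 ± 1.56 CPM.

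GZMB, whose product is the granule protease that starts apoptosis in target cells and which the study's title names, was at 41.6 ± 30.7 CPM with IL-15 and 27.4 ± 17.9 CPM without (SD, n = 3). It was higher with IL-15 in 3 of 3 same-numbered pairs, by 0.38, 0.68 and 0.58 on the log2 scale for numbers 10, 11 and 12. In the paired comparison GZMB rose 1.47-fold (log2 0.56, SE 0.08; edgeR quasi-likelihood test with the number as a block, Benjamini-Hochberg adjusted p = 0.00661). Without the block the log2 fold change was 0.60 with an SE of 0.66, and GZMB did not pass (edgeR adjusted p = 0.9997). The deposited table places GZMB on chromosome 14 from 24630954 to 24634267. Number 11 had the highest GZMB in both groups, at 47.9 and 77.0 CPM against 14.8 to 25.6 CPM in the other libraries. Without number 11 the paired log2 fold change was 0.47 and no longer passed (edgeR adjusted p = 0.0592), and without the block, leaving out the IL-15 library of number 11 gave -0.20.

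**Figure D1:**
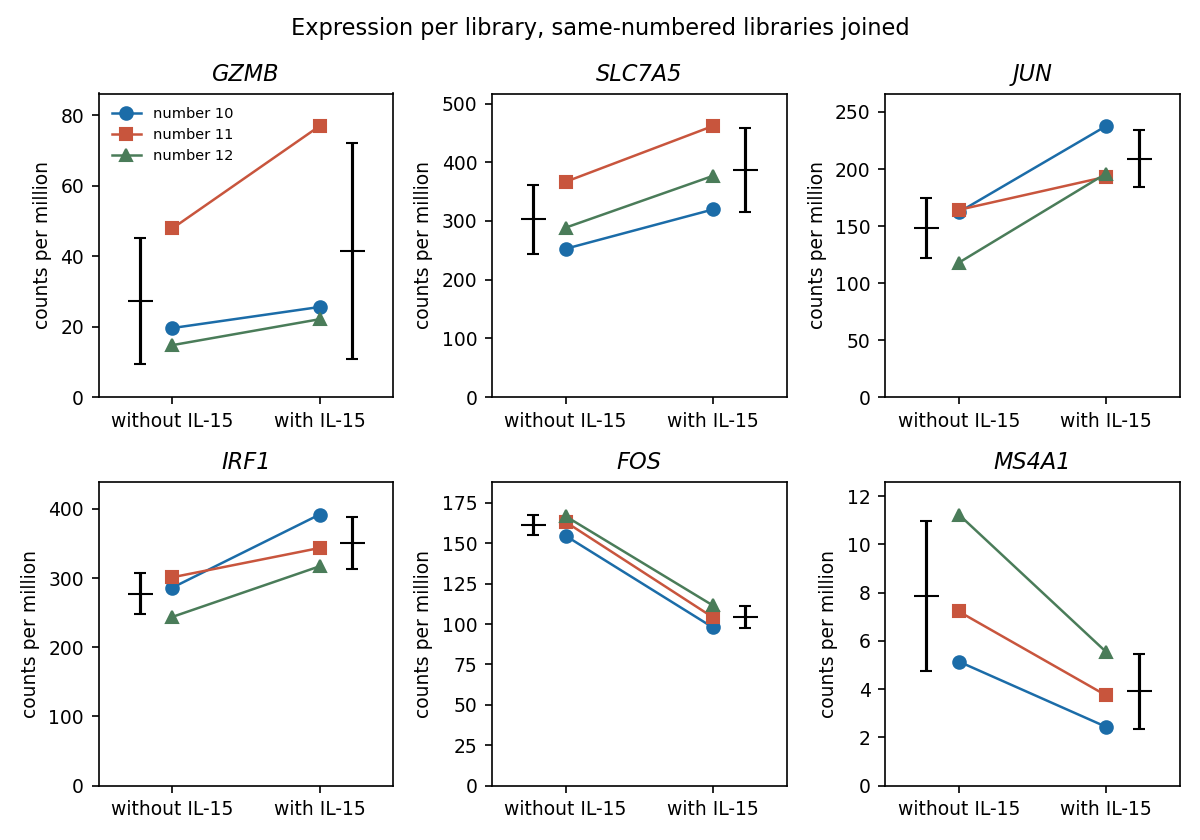
TMM-scaled CPM (y axis, linear) of GZMB, SLC7A5, JUN, IRF1, FOS and MS4A1 in the 3 libraries without and the 3 with IL-15; each line joins libraries of one number, and black bars give the group mean ± SD (n = 3). The first 4 genes are higher and FOS and MS4A1 lower with IL-15 in 3 of 3 pairs, and GZMB in number 11 lies above that in the other numbers.

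Across all genes, the question was which pathways of ILC2s respond to IL-15. FOS, a subunit of the AP-1 transcription factor, fell 1.55-fold in the paired comparison, from 161 ± 6.23 to 105 ± 6.82 CPM (log2 -0.63, SE 0.06; edgeR adjusted p = 0.000247); it lies on chromosome 14 from 75278774 to 75282230. KCNMA1, a calcium-activated potassium channel, fell 2.63-fold from 5.88 ± 1.19 to 2.24 ± 0.549 CPM (log2 -1.39, SE 0.16, edgeR adjusted p = 0.0025). STC2, a secreted glycoprotein, rose 2.13-fold from 5.24 ± 3.75 to 10.6 ± 5.92 CPM (log2 1.09, SE 0.14, edgeR adjusted p = 0.00625). In all, 36 of 13581 genes passed in the paired comparison, 23 higher and 13 lower with IL-15, each in one direction in 3 of 3 pairs. Without the block, 0 genes passed in the edgeR quasi-likelihood test, where 370 had an unadjusted p under 0.05 and the smallest adjusted p was 0.259, for FOS. Unpaired limma-voom also called 0 genes, and unpaired DESeq2 called FOS, KCNMA1 and EGR1, all lower. Higher genes changed by 1.25 to 2.13-fold (median 1.32) and lower genes by 1.24 to 2.63-fold (median 1.48), and 4 of the 36 changed by more than 2-fold.

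Higher genes included regulators of transcription and signalling. JUN, a partner of FOS in AP-1, rose from 148 ± 26.2 to 209 ± 24.9 CPM (log2 0.51, SE 0.08), HIC1, a transcriptional repressor, from 92.4 ± 14.8 to 126 ± 16.2 CPM (log2 0.46, SE 0.06) and IRF1, an interferon regulatory factor, from 277 ± 29.7 to 351 ± 37.9 CPM (log2 0.34, SE 0.06). NFKBIA, the inhibitor of NF-kappaB, rose by log2 0.35 and ASB2, a subunit of a ubiquitin ligase, by 0.49. Genes of metabolism and secretion that rose were SLC7A5, a transporter of large neutral amino acids (log2 0.35, SE 0.05), WARS, the tryptophanyl-tRNA synthetase (0.32), VEGFA, the vascular growth factor (0.34), CYP1A1, a monooxygenase (0.50), and PGGHG (0.45). Genes of surface proteins that rose were CD74, the invariant chain of MHC class II (log2 0.42, SE 0.06), CEACAM1 (0.36), CDCP1 (0.35) and PLXNA1, a semaphorin receptor (0.38). The others that rose were CES4A (0.40), FBXO41 (0.39), PDLIM7 (0.39), KIAA0895L (0.37), the noncoding RNA MIAT (0.46) and RNVU1-14 and RNVU1-19 (0.63 and 0.57), which are variants of the U1 RNA with near-identical copies, so their counts are uncertain.

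Lower genes included genes of surface proteins. MS4A1, the gene of CD20, fell 2.02-fold from 7.86 ± 3.10 to 3.91 ± 1.56 CPM (log2 -1.01, SE 0.13; edgeR adjusted p = 0.00625). IL6R, the IL-6 receptor (log2 -0.49), SIGLEC6 (-0.31) and the amyloid precursor gene APP (-0.41) also fell. The rest were DKK3 (-1.02), FREM3 (-0.69), BASP1 (-0.62), PLCL1 (-0.56), FMN1 (-0.44) and the kinase BMP2K (-0.41). Removing each library's trend with GC content ended the 10 calls of SLC7A5, JUN, IRF1, CYP1A1, FBXO41, KIAA0895L, MIAT, PDLIM7, FMN1 and RGS1, which kept 0.712 to 0.942 of their log2 fold changes (edgeR adjusted p from 0.0627 to 0.309). Leaving out number 10 ended the call of JUN (edgeR adjusted p = 0.534), number 11 ended 10 calls (0.0592 to 0.208) and number 12 ended 9 (0.0506 to 0.190), while the totals called became 405, 44 and 71. The genes whose calls ended kept 0.955, 0.844 to 1.04 and 0.922 to 0.994 of their log2 fold changes without numbers 10, 11 and 12.

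Genes of amino acid transport and of ATF4, the transcription factor of the amino acid response, stood higher together with IL-15. Of 22 measured, 20 had a positive fold change and the median was 0.17 on the log2 scale in both comparisons. The list passed without the block (limma camera adjusted p = 7.98e-06, preset correlation) and with it (adjusted p = 3.83e-08). The correlation estimated among its members was 0.36 without and 0.21 with the block, against the preset of 0.01. The p-values at the preset correlation can therefore overstate the evidence. With an estimated correlation the list did not pass (limma camera adjusted p = 0.693 without and 0.706 with the block). Nor did it pass in fry (limma fry adjusted p = 0.538 without and 0.125 with the block). Only SLC7A5 passed over all genes in the paired comparison, where 14 members were higher adjusted over the list alone, among them SLC3A2, the partner chain of SLC7A5 (log2 0.25), the serine synthesis enzyme PHGDH (0.27) and the cystine transporter SLC7A11 (0.33). Without the block 1 member passed adjusted over the list alone. Glycolysis genes were also higher, 23 of 24 with a positive fold change and a median of 0.11, but none passed singly over all genes or over the list alone. At the preset correlation that list passed with limma camera without the block (adjusted p = 4.86e-05) and with it (adjusted p = 2.99e-05). It did not pass with the estimated correlations of 0.43 and 0.35 (limma camera adjusted p = 0.693 and 0.706). GAPDH and ENO1 had log2 fold changes of 0.10 and 0.12, and of 0.03 and 0.08 with the GC trend removed. In that setting the glycolysis list did not pass (limma camera adjusted p = 0.144, median 0.08). The glycolysis call ended without number 12 in the paired comparison (median 0.07, limma camera adjusted p = 0.0805) and, without the block, on leaving out the IL-15 library of number 11 (median 0.06, adjusted p = 0.0690).

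Cholesterol synthesis genes were lower, with a median of -0.08 over 22 members, in camera without the block (adjusted p = 0.0226) and with it (adjusted p = 0.0277). With an estimated correlation the adjusted p was 0.803 and 0.706 in limma camera. In the paired comparison no member passed over all genes, and 2, CYP51A1 and SC5D, were lower adjusted over the list alone. SREBF2 and STARD4, the most abundant members, had log2 fold changes of -0.03 and -0.07; with the GC trend removed they were -0.09 and 0.06. The cholesterol call ended on leaving out number 10, 11 or 12 (limma camera adjusted p = 0.0707, 0.0541 and 0.0713), with medians of -0.07, -0.09 and -0.09. Without the block it ended on leaving out the libraries without IL-15 of numbers 10 or 11 (medians -0.04 and -0.06, limma camera adjusted p = 0.307 and 0.258) or the IL-15 library of number 12 (median -0.04, adjusted p = 0.840). Genes of FOXO1 and quiescence were lower as a list in the paired comparison alone (limma camera adjusted p = 0.00973, and 0.0698 without the block). The latter became 0.0313 or 0.0282 in limma camera on leaving out the library without IL-15 of number 10 or the IL-15 library of number 12. Of its 24 members 19 were below 0, and none passed over all genes or over the list alone. Its members include the thioredoxin inhibitor TXNIP (log2 -0.12, or -0.09 with the GC trend removed) and the IL-7 receptor IL7R (-0.14, or -0.08). With an estimated correlation the limma camera adjusted p of the list was 0.706 in the paired comparison. That estimate, -0.03, was below the preset 0.01, so the higher p did not come from members varying together.

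The cytotoxic granule and death ligand list was higher in the paired comparison (limma camera adjusted p = 0.034, and 0.269 without the block). GZMB was the only member of 21 that passed, over all genes and over the list alone. With an estimated correlation the limma camera adjusted p of the list was 0.706 in the paired comparison. That estimate, -0.02, was below the preset 0.01, so the higher p did not come from members varying together. PRF1 had a log2 fold change of 0.13 (SE 0.05) and GZMA of 0.15 (SE 0.12), or 0.06 and 0.20 with the GC trend removed, and the death ligand TNFSF10 was at 519 ± 52.3 CPM without and 518 ± 49.4 CPM with IL-15. Interferon-stimulated genes were higher in the paired comparison (limma camera adjusted p = 0.0277, and 0.162 without the block; adjusted p = 0.834 with an estimated correlation), with IRF1 as the only member of 36 that passed over all genes and 3 adjusted over the list alone. Without number 12 the median of the interferon list was -0.00 and its limma camera adjusted p was 0.949; without number 11 they were 0.03 and 0.0971, and the cytotoxic list had 0.06 and 0.198 without number 12. Without the block, the interferon list passed on leaving out the library without IL-15 of number 10 (limma camera adjusted p = 0.00648). Removing the GC trend ended the calls of the glycolysis, FOXO1 and cytotoxic lists (limma camera adjusted p = 0.144, 0.116 and 0.145), with medians of 0.08, -0.06 and 0.06 against 0.11, -0.08 and 0.08 before, and left the amino acid, cholesterol and interferon lists past the threshold (adjusted p = 0.000151, 0.00677 and 0.0472). With an estimated correlation in that setting, the limma camera adjusted p of each of these 3 lists was 0.758.

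**Figure D2:**
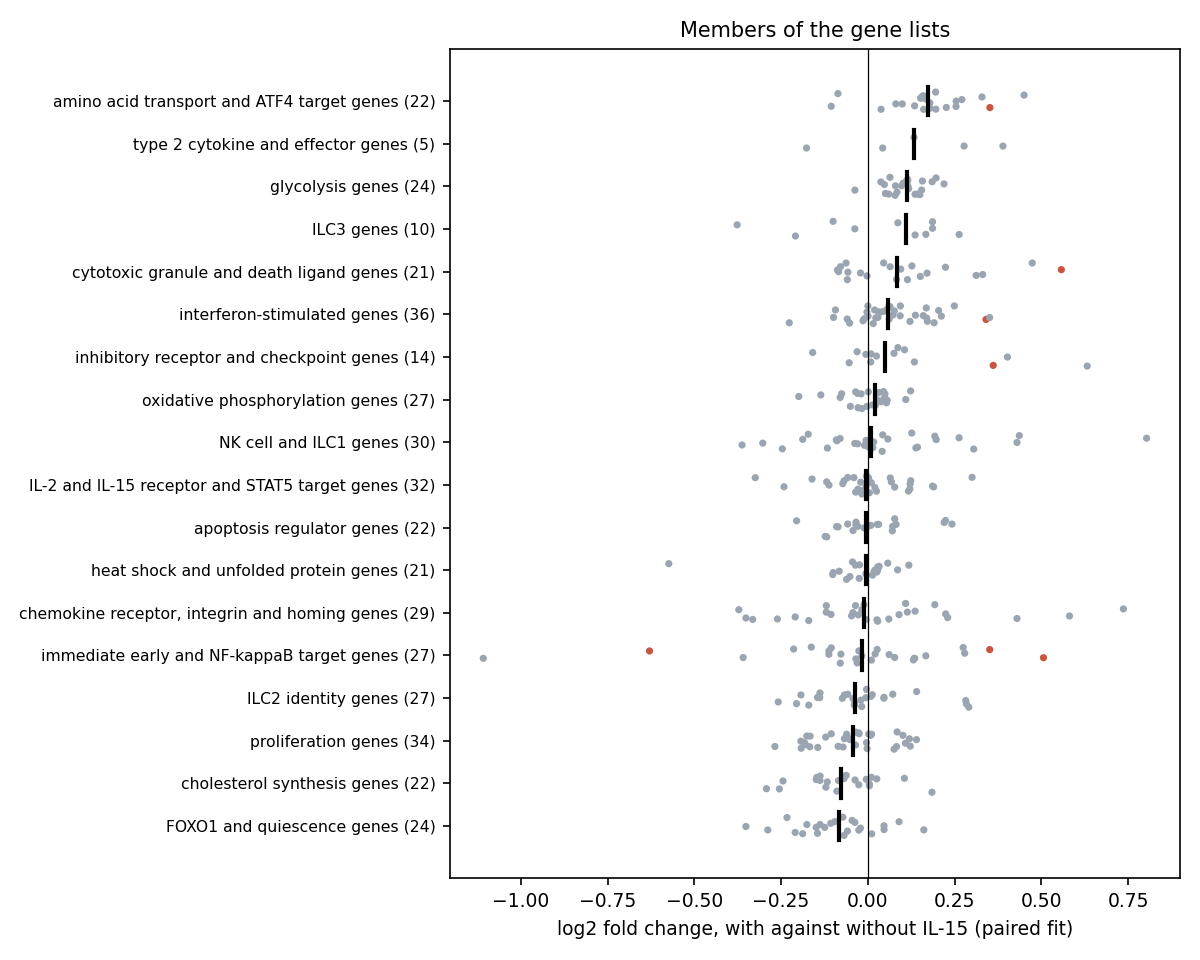
Log2 fold change with against without IL-15 in the paired comparison (x axis) of each measured member of 18 gene lists (y axis, number of members in parentheses); each point is a gene, red points passed over all genes and black bars are list medians. The amino acid and ATF4 list has a median of 0.17 and the FOXO1 list of -0.08.

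Genes that define ILC2s and their type 2 products did not pass in either comparison. GATA3 was at 876 ± 23.2 CPM with IL-15 (log2 -0.04, SE 0.05 in the paired comparison), KIT at 2036 ± 281 CPM (-0.19, SE 0.06), KLRG1, an inhibitory lectin receptor, at 64.8 CPM (0.01, SE 0.06) and IL13 at 97.9 ± 22.3 CPM (0.04, SE 0.07). Of 27 measured ILC2 identity genes 0 passed over all genes in the paired edgeR test, where 4 higher and 5 lower had an unadjusted p under 0.05, and 3 were higher and 4 lower in the paired comparison adjusted over the list alone. CRLF2 and IL9R of that list were listed at 0 in all libraries. The 14 genes that the table places in pseudoautosomal parts of chromosome X, CRLF2 among them, were all at 0, and the highest of 5 widely used pseudoautosomal genes was 0.0284 CPM in any library. TBX21, the regulator of type 1 lymphocytes, was at 9.78 ± 0.842 CPM with and 7.93 ± 0.960 CPM without IL-15 (log2 0.31, SE 0.11 in the paired comparison) and did not pass. Neither did IL2RB, the receptor chain for IL-2 and IL-15 (0.19, SE 0.05), the activating receptor CD226 (-0.09, SE 0.06) or FOXO1 (0.01, SE 0.07). With the GC trend removed IL13 was -0.01, CD226 0.01, KLRG1 0.07, GATA3 -0.08, KIT -0.14, IL2RB 0.13 and TBX21 0.23 on the log2 scale, none of them past the threshold.

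The immediate early and NF-kappaB list went in both directions. JUN and NFKBIA rose and FOS fell of 27 members in the paired comparison, and adjusted over the list alone 3 were higher and 1 lower, or 1 higher and 2 lower without the block. CEACAM1 was the only one of 14 inhibitory receptor and checkpoint genes that passed in the paired comparison, over all genes and over the list alone. Without the block 1 of the 14 was higher adjusted over the list alone. Lists of type 2 cytokine, NK cell and ILC1, ILC3, IL-2 and IL-15 receptor and STAT5, proliferation, oxidative phosphorylation, apoptosis, homing and heat shock genes did not pass with camera in either comparison, nor did the immediate early and inhibitory receptor lists. No member of the 9 lists named first passed over all genes. Adjusted over the list alone in the paired comparison, 1 NK cell and ILC1 gene was higher and 2 were lower, 4 homing genes and 1 heat shock gene were lower, and 0 members of the others passed. In the paired comparison proliferation genes passed without number 12 (limma camera adjusted p = 0.00992), NK cell and ILC1 genes without number 11 (0.0256) and oxidative phosphorylation genes without number 10 (0.0448). Without the block, leaving out the library without IL-15 of number 10 let type 2 genes pass (limma camera adjusted p = 0.0380), that of number 12 proliferation and heat shock genes (6.03e-07 and 0.0334), and the IL-15 library of number 10 inhibitory receptor genes (0.0488). Median, mean and test differed in sign for 4 lists in each comparison, namely STAT5, apoptosis, homing and B cell genes.

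Markers of other cell types did not pass over all genes, apart from MS4A1. Of the T cell genes, CD3E was at 79.9 ± 18.0 CPM without IL-15, while CD3D averaged 8.03, CD3G 0.548 and CD4 0.0798 CPM of all counts over 6 libraries. CD79B was at 29.3 ± 3.14 CPM without and 29.2 ± 3.12 CPM with IL-15, and CD79A averaged 0.367 CPM of all counts. Of the myeloid genes, ITGAX was at 81.9 ± 6.59 CPM without IL-15 and VCAN had a paired log2 fold change of 0.64 (SE 0.13; edgeR adjusted p = 0.0934). Of the stromal genes, VIM, which lymphocytes also express, was at 2441 ± 241 CPM without IL-15 and COL1A1 averaged 0.313 CPM of all counts. None of the 4 tested marker lists passed with camera in either comparison; fry called the set of 3 measured B cell genes in the paired comparison (limma fry adjusted p = 0.0105), whose members went different ways, MS4A1 with -1.01, CD79B with -0.01 and CD79A with 1.03 on the log2 scale (SE 0.46 for CD79A; edgeR adjusted p = 0.460). Adjusted over the list alone, MS4A1 and 2 myeloid genes, VCAN and AIF1 (log2 1.35, SE 0.47), passed in the paired comparison, and the myeloid list passed with camera without number 10 (limma camera adjusted p = 0.0134) and, without the block, on leaving out the library without IL-15 of number 11 (0.00786) or the IL-15 library of number 10 (0.00255). The basophil and mast cell and the erythroid and platelet lists had 1 measured member each and were not tested.

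Fold changes went with GC content and, less evenly, with gene length. Across 9665 genes, the log2 ratio of with over without IL-15 correlated with GC content at a Spearman coefficient of 0.61 in number 10, 0.45 in number 11 and 0.10 in number 12; genes are not independent replicates. With the deposited gene length the coefficients were 0.14, -0.42 and -0.14. In number 10 the median log2 ratio went from -0.17 in the 2417 genes with the lowest GC content to 0.13 in the 2416 with the highest. Genes that rose had a median GC content of 54.6%, genes that fell of 48.7% and all tested genes of 48.6%.

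**Figure D3:**
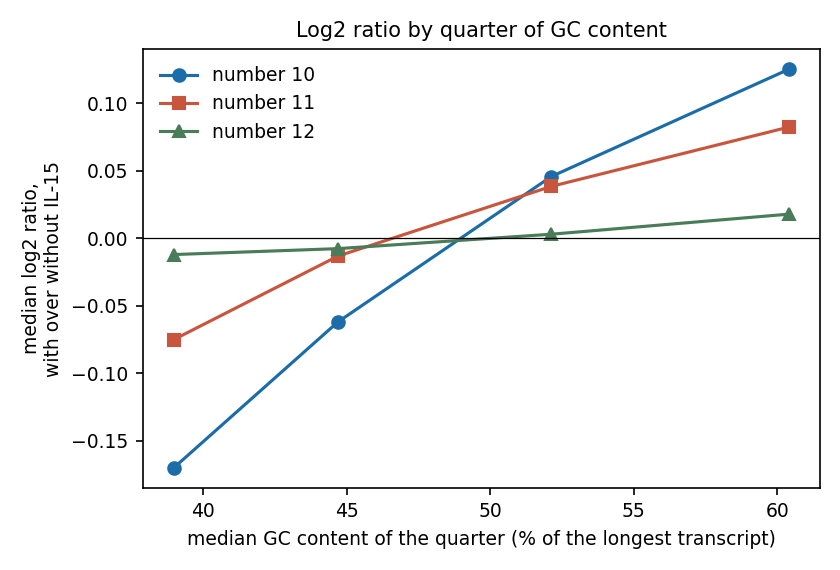
Median log2 ratio of with over without IL-15 (y axis) in 4 bins of genes by GC content (x axis, median percent of each bin), 1 line per number. The lines for numbers 10 and 11 climb from -0.17 and -0.08 to 0.13 and 0.08, and that for number 12 from -0.01 to 0.02.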

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

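All alternatives of the paired comparison were added after seeing the data; those without the block were planned. Without the block, the count of 0 genes held with RLE factors, total counts, limma-voom, both filters and each library left out. Both stricter thresholds could only give 0 again, so they test nothing here. DESeq2 called 3 (0 higher, 3 lower), and the replicate block called 36 (23 higher, 13 lower). GZMB was 0.56 with the block, and leaving out a library moved it from -0.20 (without the IL-15 library of number 11) to 1.27 (without the other library of number 11), never past the threshold. The number of lists past the threshold, 3, was 6 with the block, 0 with an estimated correlation, 0 with fry and 2 to 5 with a library left out; glycolysis ended without the IL-15 library of number 11 (limma camera adjusted p = 0.069).

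In the paired comparison the 36 calls (23 higher, 13 lower) became 98 (62 and 36) with no filter, 14 (8 and 6) at an adjusted p of 0.01, 4 (1 and 3) with a minimum fold of 2, and 27 with 15 higher on total counts. Paired DESeq2 gave 29 higher and 10 lower. Total counts ended CDCP1, CEACAM1, FBXO41, FMN1, IRF1, JUN, KIAA0895L, MIAT and NFKBIA (edgeR adjusted p from 0.0506 to 0.113). DESeq2 ended BASP1, DKK3, FMN1 and KIAA0895L (DESeq2 adjusted p from 0.0532 to 0.184). These genes kept 0.971 to 1.03 of their log2 fold changes on total counts and 0.992 to 1.00 in DESeq2. The stricter filter left DKK3 and KCNMA1 untested and ended JUN and MIAT (edgeR adjusted p = 0.0625 and 0.0705). With a number left out the counts were 44 to 405, 26 to 176 higher and 18 to 229 lower, with fewer pairs; the cause was not tested. All 36 genes were among the 98, and 35, 26 and 27 were called without numbers 10, 11 and 12. JUN ended without number 10. Without number 11 CEACAM1, FMN1, GZMB, KIAA0895L, NFKBIA, PDLIM7, RNVU1-14, RNVU1-19, SIGLEC6 and WARS ended, and without number 12 CEACAM1, FBXO41, FMN1, IL6R, IRF1, SIGLEC6, SLC7A5, VEGFA and WARS. Of the 36, 20 passed at the 0.05 threshold in every paired fit of the 6 libraries (RLE, total counts, DESeq2, limma-voom, both filters, GC trend removed) and 13 also without each number. GZMB ranged from 0.47 to 0.65, ending without number 11. The number of lists past the threshold, 6, was 3 with no filter, 3 with the GC trend removed, 0 with an estimated correlation, 1 with fry (B cell genes, not among the 6) and 3 to 7 with a number left out; cholesterol synthesis ended without any 1 number. No called gene changed sign and no called list changed camera's direction, but uncalled values did: named genes 60 times without the block and 42 with it, lists 29 and 21 times. The share in the 10 most abundant genes differed by 0.261 percentage points between groups. On simulated counts at this depth, with changed genes above a log2 CPM of 3, the test without the block recovered 58% of genes changed 1.5-fold. It called 0 unchanged genes. With the block the test recovered 99% and called 13 unchanged genes. Smaller changes of single genes, such as the median of 1.32-fold among the higher calls, were not simulated.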

Other observations

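The genes named in the next sentences were chosen after their values were seen; the tests of GC content, pseudoautosomal genes and splits were set before their results. Adjusted over the list alone, the paired comparison placed the ILC2 genes NMUR1, the neuromedin U receptor (log2 0.29, SE 0.06), TNFRSF25, the receptor of TL1A (0.28, SE 0.06), and IL17RB, the IL-25 receptor chain (0.28, SE 0.07), higher with IL-15. RORA (-0.26, SE 0.06), KIT (-0.19, SE 0.06), CYSLTR1 (-0.21, SE 0.07) and CCR4 (-0.17, SE 0.06) were lower. Of the homing genes, GPR183 (-0.33), CD69 (-0.26) and S1PR1 (-0.21) were lower by the same adjustment. None of these 10 genes passed over all genes tested (edgeR adjusted p from 0.0896 to 0.347).

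The 36 calls of the paired comparison came with a trend of fold changes with GC content across the libraries. After that trend was removed, the 36 genes kept a median share of 0.915 of their fold change (quartiles 0.833 and 0.980). The trend as removed thus made up the smaller part of their fold changes. These genes were chosen for passing, and so for large changes, beside which the trend was small. The share kept therefore cannot show whether the trend helped genes pass. Once the trend was removed 10 calls ended, and 31 genes passed (18 higher, 13 lower), 26 of them among the 36. Genes with an unadjusted edgeR p under 0.05 went from 1423 to 906. A trend with gene length was not removed and stays open. In the 10 genes whose calls ended the fold change was smaller, by shares kept of 0.712 to 0.942, with medians of 0.39 before and 0.31 after, and the SE (medians 0.07 and 0.06) was smaller in 8 genes and larger in JUN and CYP1A1. Whether the trend itself comes from the libraries or from IL-15 cannot be told apart: libraries of one group reached a correlation of 0.440, below the bound (0.452, the median of the 3 same-numbered pairs), but by 0.0114 against an SD of 0.139, a margin added after the value was seen. Splits are too few to give a share under 0.05: 1 of the 4 splits that part all pairs, the real one, gave 36 genes against at most 3 in the others, and without the block 10 of 10 splits gave at least the real 0, the highest other giving 1.

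For the higher amino acid and ATF4 list, the same GC trend is a candidate explanation. With it removed the median log2 fold change was 0.140, against 0.174 before, and the list still passed with a preset correlation (limma camera adjusted p = 0.000151). The GC trend as removed thus made up the smaller part of the median. GC content came from the longest transcript alone and the trend with gene length was not removed. A trend between the libraries is therefore not excluded. With an estimated correlation in the same setting the list did not pass (limma camera adjusted p = 0.758). No list passed there, so that result cannot decide. A response of ILC2s to IL-15 remains a hypothesis, since a trend between the libraries stays open.

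CRLF2 and IL9R were listed at 0, and 5 widely used pseudoautosomal genes, SLC25A6 and AKAP17A among them, reached at most 0.0284 CPM in any library, so reads of these genes may not have been counted and the zeros say nothing of expression.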
